A study of Oryza sativa with 36 samples.

How the data were processed

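Transcript levels were measured in rice anthers with single-colour (Cy3) oligonucleotide arrays. Per the labels, each extract came from anthers at 1 stage of pollen development, and the 3 replicates of a group came from independent plants. The 36 arrays form 12 groups, namely 6 lines at 2 stages with 3 arrays each.

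The deposited scanner files hold spot intensity values from the image software, after background subtraction and detrending within each array, beside the raw spot and local background intensity. The authors also deposited a value table of signal on a linear scale, whose values matched the background-subtracted spot signal times 1 constant per array, with the 75th percentile of every array at 10 and a lower limit of 0.01. The other deposited columns used here were 0 or 1 flags for spots well above background, saturated spots and outlier spots. The submitters' notes name limma and R 2.9.1 without saying for which step. The image software version differed between the stages (9.5.1.1 at the first, 9.5.3.1 at the second, per the file headers).

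The choices below were made before the data were examined, except where a sentence says otherwise. The processed intensity was put on the log2 scale and the 75th percentile of each array was subtracted. Spots with an outlier flag were set to missing, which was 26 to 89 spots per array, and the spots of a probe were averaged. Each locus was represented by its brightest probe over all 36 arrays. A locus was tested if its probe was well above background on all 3 arrays of at least 1 of the 12 groups, which left 26645 loci. The array annotation gave 41908 probes a locus, for 29690 loci, of which 7801 had several probes. The 569 probes without a locus were not in the comparisons, and 510 of them are for microRNA genes (the mature sequence or the 5′ or 3′ sequence, per their names).

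A linear model with 1 mean per group was fitted across all genes with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes), with the data.table package (1.17.8) for reading. Each CMS line was compared with T65 of the same stage, which gave 10 comparisons, and T65 was compared between its 2 stages. The difference between a line's change at BC and its change at UN was tested as an interaction. Differences among the 5 CMS lines at a stage were tested by the moderated F test over 4 contrasts. The p-values were two-sided and were adjusted by the Benjamini-Hochberg method within each comparison. A gene was called where its adjusted p was under 0.05 and its change was at least 2-fold, or, for the F test, where the highest and the lowest line mean were at least 2-fold apart. Every SE is that of the moderated fit. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

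Gene lists for 26 groups were fixed from knowledge of rice genes and from words in the descriptions. They were tapetum regulators, pollen wall and sporopollenin, meiosis, starch synthesis, sugar transport and invertases, pollen MIKC* MADS, perianth and carpel markers, alternative oxidase, single genes of earlier CMS work, pectin enzymes, pollen allergens and expansins, actin cytoskeleton, mitochondrial respiratory complexes, pentatricopeptide repeat proteins, mitochondrial carriers and import, heat shock and chaperones, antioxidant enzymes, photosynthesis, cytosolic ribosomal proteins, histones, lipid transfer proteins, phenylpropanoid and flavonoid enzymes, proteases and inhibitors, jasmonate pathway, calcium signalling, and cell division. A list with at least 3 measured loci was tested by limma's camera with a preset correlation of 0.01, adjusted over 264 tests (24 lists in 11 comparisons). Camera with an estimated correlation and fry were run beside it. Missing spots took their group's mean for these tests alone. Of the 264 tests, 68 were called with the preset correlation, 1 with an estimated correlation (heat shock and chaperones in CW at BC) and 117 by fry, and 58 by both camera with the preset correlation and fry. Genes are named by locus and by the description on the array. Symbols such as PKS1, GBSSI or AOX1a were assigned to loci from memory, since the gene table supplied with the files matched 0 of the loci. No genome was at hand, so no coordinates are given. Locus Os04g0310500 (ACOS12) and locus Os01g0720600 (SSIVa) were left out of their lists because the array describes another kind of protein there.

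The named genes followed a rule. Per stage, it takes the 10 highest and the 10 lowest genes by mean change among those called the same way in all 5 lines. Per line and stage, it takes the 4 most raised and the 4 most lowered of the called genes whose 3 arrays lay above or below all 3 T65 arrays, apart from those. For the T65 stage change it takes the 10 most raised and the 10 most lowered genes. It further takes up to 4 called members of each list with the largest absolute change, and the loci listed here as AOX1a, DCW11, RMS and RF2 whatever their values. Genes without a described product were not taken, and the text names part of each set from its top downward.

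The arrays were on 10 slides and were scanned on 6 days, with slides and days of 1 stage only. The stages therefore cannot be told apart from slides, days and software versions, and the line comparisons, which lie within a stage, were also fitted with the slide or the scan day as a block. Residuals of arrays of different groups on 1 slide had a mean correlation of 0.19 at UN and 0.34 at BC, against −0.04 and −0.08 on different slides. The genes of each line comparison were also called without the line array and the T65 array of a slide they share and read on these 2 arrays. This test and the simulations with shared slides or scan days were added after seeing the data. Signal over local background had medians of 3.2 to 8.62 over the arrays, 75.0% to 88.6% of the 43734 spots that are not controls were well above background and 0 spots were saturated. The number of arrays limits the precision.

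The alternatives tried were normexp background correction with an offset of 50, quantile normalization, the deposited value table, no filter, a filter for spots well above background on all 36 arrays, every probe tested on its own, outlier spots kept, the replicate number, the slide or the scan day as a block, only the groups compared, eBayes with trend and robust, camera with an estimated correlation, and leaving out each array in turn. A fit without 4 arrays (CW BC replicate 3, T65 BC replicate 1, BT UN replicate 1 and CW UN replicate 3) was added after seeing the data. They were chosen by eye on the first principal component, by no numeric rule: CW UN 3 correlated best with an array of its own group, and BT BC 3 and LD BC 1, which correlated best with an array of another group, were kept. Normexp moved the median change of all genes by more than 0.1 log2 units in most comparisons, to 0.40 in BT, 0.48 in CW and 0.07 in WA at UN, to −0.40 in BT, −0.37 in CW, −0.40 in LD, −0.43 in W11 and −0.50 in WA at BC, and to 0.45 for the T65 stage change. Quantile normalization moved it to −0.15 in WA at UN. The medians as reported lay between −0.10 and 0.09.

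The fit was tested on simulated data of 26645 genes, of which 67, 67 and 66 were given changes of 1.5, 2 and 3 log2 units. Of these it recovered 64.2%, 77.6% and 90.9% in the comparison of BT at UN, with 3 false calls. The interaction of BT gave 55.2%, 74.6% and 84.8% with 11 false calls, and the F test at UN gave 64.2%, 88.1% and 90.9% with 4 false calls. These simulated arrays had the same spread of a gene in every group and no slide effect, so real false calls may be more. In 5 simulations per stage without any change that kept each group's own spread, 1 comparison gave up to 48 calls at UN and 191 at BC.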

Results

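The series measured transcript levels in rice anthers of 5 cytoplasmic male sterile (CMS) lines and of T65, the wild-type control. In CMS, the mitochondria of the cytoplasm make the pollen sterile. The CMS lines are BT, CW, LD, W11 and WA. Anthers were taken at 2 stages, the uninucleate microspore (UN) and bicellular pollen (BC), with 3 arrays per line and stage and 36 arrays in all. Each array held 45151 spots. Of the 43734 that are not controls, 75% to 88.6% were well above background, and 26645 loci were tested. Per its title, the series asks how expression profiles differ among 5 independent CMS lines. Every change below is a log2 difference, from T65 of the same stage unless another comparison is named, given ± its SE with n = 3 arrays per group. The arrays' number limits the precision.

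The 6 lines did not form 2 plain stage groups. On the first principal component, which held 50.6% of the variance of the 5000 most variable genes, the UN arrays of T65 and W11 lay between −120.7 and −104.7, and the BC arrays of BT, LD and W11 between 136.6 and 193.2. The T65 BC arrays lay at 51.9, −9.4 and −40.9. The WA arrays stood apart on the second component (20.1%), at 151.5 to 171.3 at BC and 75.2 to 93.8 at UN. The highest array of another line was at 47.1. The arrays BT UN 1, BT BC 3, CW BC 3, LD BC 1 and T65 BC 1 were each nearest to an array of another group.

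**Figure D1:**
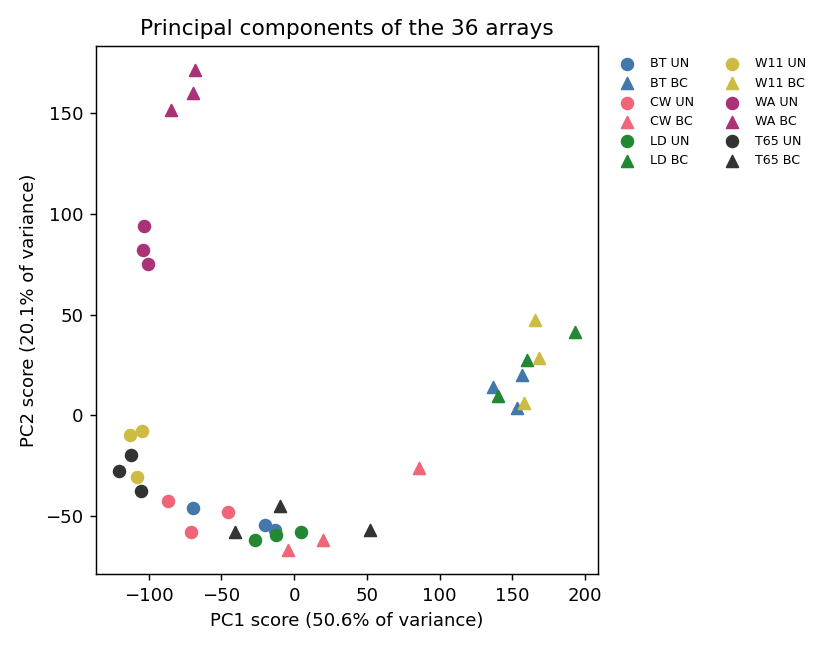
Each point is an array, placed by its scores on the first (50.6% of the variance) and second (20.1%) principal components of the 5000 most variable genes, with lines by colour and stages by symbol. The WA arrays stand apart on the second component, at 151.5 to 171.3 at BC and 75.2 to 93.8 at UN.

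In the fertile control T65, pollen wall genes and tapetum genes fell from UN to BC. This comparison gives the course of the control between the stages. PKS1 (Os10g0484800), a polyketide synthase of sporopollenin synthesis, fell by 13.70 ± 1.25 log2 units (adjusted p = 1.62e-08), and an AMP-dependent synthetase and ligase domain gene (Os04g0310800) fell by 12.15 ± 1.47. AP25 (Os03g0186900), an aspartic protease of the tapetum, the cell layer that feeds the microspores, fell by 10.81 ± 1.33, and CYP704B2 (Os03g0168600), a cytochrome P450 of sporopollenin synthesis, fell by 10.70 ± 1.20. A plastocyanin-like domain gene (Os06g0553800) rose by 11.40 ± 1.59, a plasma membrane H+ ATPase (Os05g0319800) by 9.45 ± 0.60 and the pollen specific protein C13 (Os04g0398700) by 9.41 ± 0.96 (adjusted p = 7.87e-08). PKS1 was above background on 1 of 3 BC arrays and Os04g0310800 on 2 of 3, while Os06g0553800 was above it on 1 of 3 UN arrays and the ATPase on 2 of 3, so these changes have a floor at 1 end.

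Of the pollen wall and sporopollenin list, 7 of 13 members fell and 0 rose (median −2.56, adjusted p = 0.000237). Of the tapetum regulators, 7 of 12 fell and 1 rose (median −1.44, adjusted p = 0.0157). Cytosolic ribosomal proteins went up as a list (18 of 240 members rose, 1 fell; median 0.48, adjusted p = 1.19e-13), as did the mitochondrial respiratory complexes (5 of 46 rose, 0 fell; median 0.44, adjusted p = 6.64e-05) and the histones (8 of 47 rose, 0 fell; median 0.50, adjusted p = 0.00865). With an estimated correlation the adjusted p of these 5 lists was, in that order, 0.603, 0.607, 0.608, 0.67 and 0.749, and with normexp the call of the histones was lost. In all, 2282 genes rose and 2487 fell. Each stage was on its own slides, so no value within a slide can be had. The slide as a random block gave 4923 genes, the scan day 4845 and the fit without 4 arrays chosen by eye after seeing the data 3639, and normexp called 2104 higher and 851 lower.

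At UN, pollen wall and tapetum genes fell in BT, CW and LD, and genes that rise toward BC in T65, such as the plasma membrane H+ ATPase, were already higher. The comparisons at this stage ask how each CMS line differs from T65 at the uninucleate microspore. In BT, Os04g0310800 fell by 11.62 ± 1.47 (adjusted p = 2.44e-06), a cytochrome P450 (Os04g0570600) fell by 10.34 ± 1.49 and CYP704B2 fell by 9.51 ± 1.20. In LD, Os04g0570600 fell by 11.69 ± 1.49 and PKS1 fell by 11.01 ± 1.25 (adjusted p = 3.94e-07). In CW, a glycoside hydrolase of family 5 (Os02g0596200) fell by 7.54 ± 1.20 and Os04g0310800 fell by 7.06 ± 1.47 (adjusted p = 0.00172). The plasma membrane H+ ATPase rose by 7.83 ± 0.60 in BT, 7.45 in CW and 9.29 in LD (adjusted p = 4.42e-09, 2.83e-08 and 8.68e-11), and Os06g0553800 rose by 8.82 ± 1.59 in CW and 11.54 in LD. Os06g0553800 was above background on 1 of 3 T65 UN arrays, the ATPase on 2 of 3, Os04g0310800 on 2 of 3 BT arrays and Os04g0570600 on 1 of 3 LD arrays.

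**Figure D2:**
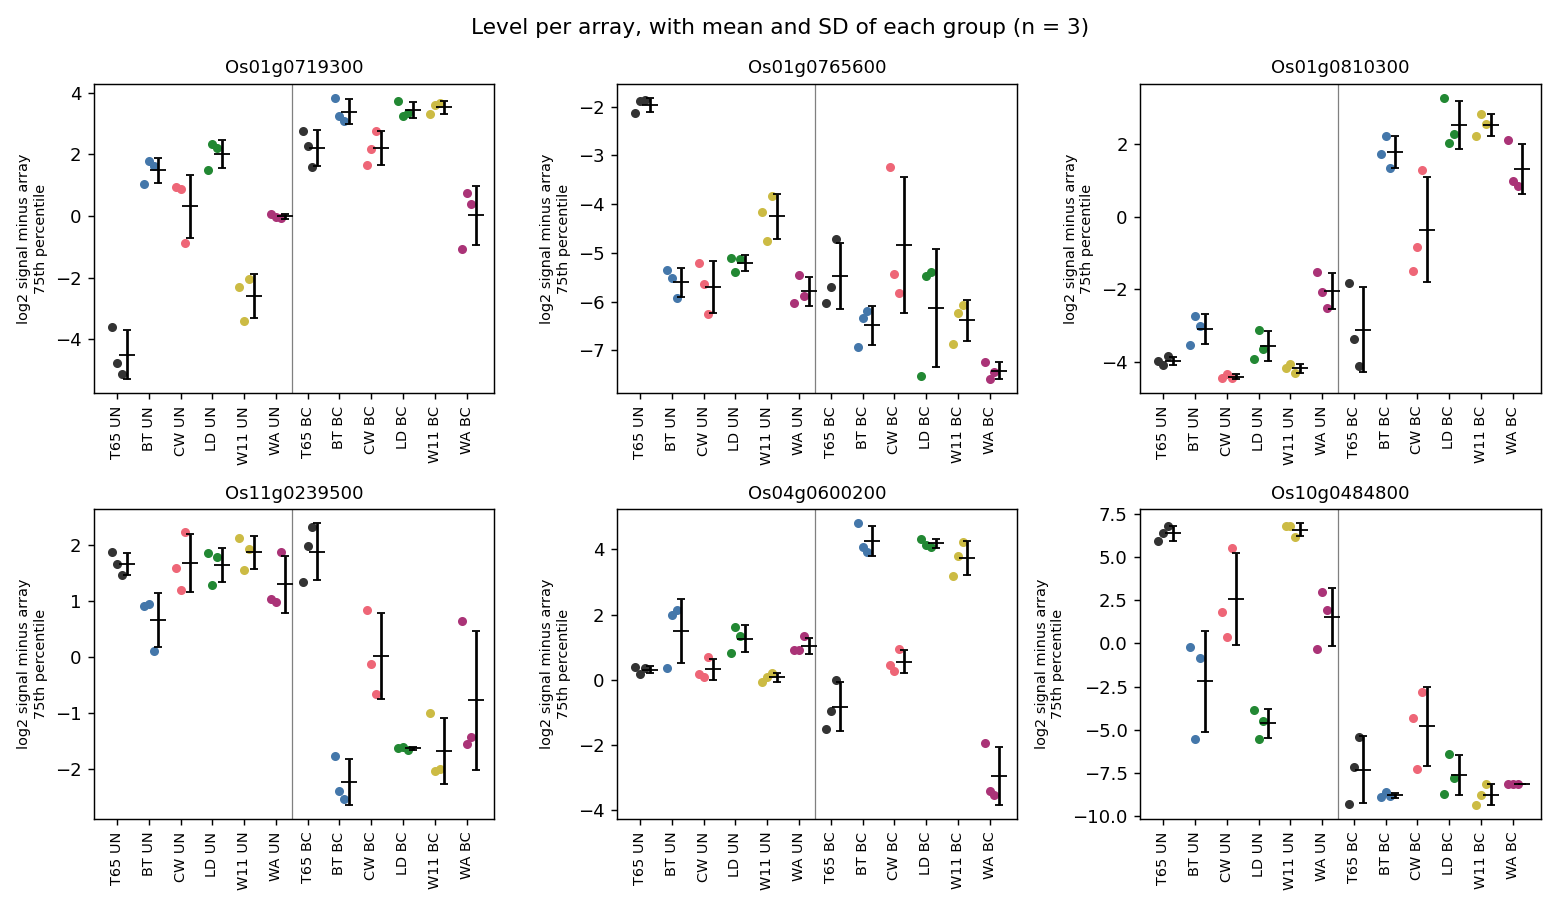
Each panel shows a gene's level (log2 signal minus the array's 75th percentile) in the 12 groups, a point per array with the mean and SD of 3 arrays. PKS1 (Os10g0484800) is high at UN in T65 and W11, lower in BT and LD, and low in all lines at BC.

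Of the 13 pollen wall and sporopollenin genes, 7 fell in BT, 7 in CW and 6 in LD, and 0 rose. The list's median was −2.53 in BT (adjusted p = 0.00035), −1.58 in CW (0.000821) and −1.79 in LD (0.000105); with an estimated correlation the adjusted p was 0.603, 0.607 and 0.603. ABCG15 (Os06g0607700), a transporter of wall precursors, fell, with changes of −8.86 ± 1.10 in BT, −4.48 in CW and −9.93 in LD, and PKS1 fell as well, with −8.59 ± 1.25 in BT and −3.82 in CW. Of the 12 tapetum regulators, 4 fell and 1 rose in each of these lines (median −0.50, −0.57 and −0.63 in BT, CW and LD; adjusted p = 0.0254, 0.021 and 0.0254, and 0.607 in each with an estimated correlation). The call in LD was lost with quantile normalization. Among the tapetum regulators, AP25 fell by 9.28 ± 1.33 in BT, and AP37 (Os04g0448500), another aspartic protease, fell in all 3 lines, with −7.81 ± 1.43 in BT, −6.65 in CW and −7.84 in LD.

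Meiosis genes rose as a list in BT (6 of 16 higher, 0 lower; median 0.68, adjusted p = 0.00338) and LD (6 higher, 1 lower; median 0.85, adjusted p = 0.00801), with an adjusted p of 0.607 in both with an estimated correlation. The call in LD was lost with normexp. In CW, 3 meiosis genes were higher and the list was not called by camera (adjusted p = 0.0508, and 0.00654 by fry). Cytosolic ribosomal proteins went up in BT (4 of 240 higher, 2 lower; median 0.37, adjusted p = 6.6e-09), CW (2 and 0; median 0.42, 2.47e-17) and LD (12 and 2; median 0.39, 4.72e-10), with an adjusted p of 0.675, 0.607 and 0.67 with an estimated correlation. Starch synthesis genes rose as a list in LD (6 of 24 higher, 0 lower; median 0.43, adjusted p = 0.00826, and 0.607 with an estimated correlation), where GBSSI (Os06g0133000), the granule-bound starch synthase, rose by 5.17 ± 0.89. Respiratory complex genes went up in LD too (3 of 46 higher, 0 lower; median 0.23, adjusted p = 0.0362, and 0.84 with an estimated correlation).

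The photosynthesis list went down in LD (20 of 82 lower, 10 higher; 23 and 11 adjusted over the list alone; median −0.54, adjusted p = 0.00163, and 0.675 with an estimated correlation), and psaK (Os07g0148900), a photosystem I subunit, fell by 6.62 ± 0.65 there. Its most raised member in BT, CW and LD was a plastocyanin-like domain gene (Os02g0725500), which rose by 11.31 ± 0.69, 10.29 and 12.52; proteins with this domain are not all of photosynthesis. In CW, pectin enzymes went down as a list (12 of 81 lower, 2 higher; median −0.16, adjusted p = 0.0197, and 0.67 with an estimated correlation), a call that normexp ended, with a median of 0.79. Histones went up in CW (4 of 47 higher, 0 lower; median 0.35, adjusted p = 0.0309, and 0.813 with an estimated correlation), and normexp ended that call too. A small heat shock gene (Os02g0758000) rose in these lines, by 6.87 ± 0.56 in BT, 4.23 in CW and 7.75 in LD, whereas the list of 164 heat shock and chaperone genes was not called by camera (fry called it in BT and LD, adjusted p = 0.0169 and 0.00137).

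The changes of BT, CW and LD at UN ran along the T65 change from UN to BC. Across genes, which are not independent replicates, the correlation with the T65 stage change was 0.81 in BT, 0.77 in CW and 0.88 in LD, against 0.37, 0.40 and 0.46 in simulations without any change, where the shared T65 UN arrays alone give a correlation. In BT, 1256 genes were higher and 1175 lower in both, where 156 and 146 were expected of independent calls. The lines also shared genes with each other. BT and LD had 1421 genes higher and 1157 lower in common (158 and 91.9 expected), with a covariance of 1.04 against 0.0612 simulated, BT and CW had 835 and 698 (73.6 and 53.8 expected), and CW and LD had 812 and 670 (93.1 and 53.8 expected). Part of this excess may come from the shared T65 arrays. In W11 and WA the correlation with the T65 stage change was 0.25 and 0.29, against 0.40 and 0.44 simulated, with a covariance of 0.174 and 0.429, against 0.0612 and 0.0608 simulated. Of the called genes, 176 were higher in both and 106 lower in both in W11 (47.9 and 24.8 expected if independent) with 42 called opposite, and 550 and 718 in WA (256 and 152 expected) with 427 called opposite.

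W11 at UN was higher than T65 in photosynthesis genes, and none of its pollen wall or tapetum genes passed the test. Of the pollen wall list and of the tapetum list, limma called 0 members in W11, and 2 and 1 had an unadjusted p under 0.05. Neither list was called (adjusted p = 0.772 for both by camera, and 0.635 and 0.555 by fry), with PKS1 at 0.21 ± 1.25 and CYP704B2 at 0.04 ± 1.20. The most raised genes were an alpha-amylase (Os08g0473900; 5.72 ± 0.91, adjusted p = 0.000175), a gene described as PV72 (Os11g0190700; 5.65 ± 0.88) and a Myb factor (Os04g0583900; 4.82 ± 0.68). The most lowered were a gene with a lipid transfer protein domain (Os03g0357500; −4.82 ± 1.22, adjusted p = 0.0135) and a cellulase (Os03g0108300; −3.28 ± 0.86). The amylase was above background on 2 of 3 T65 arrays and the PV72 gene on 1 of 3. Of the photosynthesis list, 17 of 82 members rose and 1 fell (24 and 1 adjusted over the list alone; median 0.46, adjusted p = 1.15e-12, and 0.603 with an estimated correlation). Respiratory complexes (median −0.19, adjusted p = 0.0301) and cytosolic ribosomal proteins (median −0.17, adjusted p = 0.000235) went down as lists with 0 members called by limma (7 and 33 lower, and 2 and 3 higher, at an unadjusted p under 0.05), with an adjusted p of 0.84 for both with an estimated correlation and of 0.191 and 0.184 by fry. The call of the respiratory complexes was lost with quantile normalization and with the slide as a block.

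In WA at UN, pollen wall and tapetum genes fell, while a late embryogenesis abundant protein and a thaumatin-like protein were among the genes that rose most. A gene described as GRAB2 (Os07g0684800) rose by 9.18 ± 0.79 (adjusted p = 1.38e-09), a glycoside hydrolase of family 5 (Os10g0370500) by 8.90 ± 0.75, the late embryogenesis abundant protein Os01g0314800 by 8.78 ± 0.84, and a thaumatin-like protein (Os03g0663400) by 8.66 ± 0.69. CYP703A3 (Os08g0131100), a sporopollenin P450, fell by 9.32 ± 1.14 (adjusted p = 3.85e-07), and Os02g0596200 fell by 8.56 ± 1.20. GRAB2 was above background on 2 of 3 T65 arrays and Os10g0370500 on 1 of 3. Of the pollen wall list, 8 of 13 fell and 0 rose (median −3.66, adjusted p = 3.33e-05), and of the tapetum list 7 of 12 fell and 0 rose (median −1.37, adjusted p = 0.000473), both with an adjusted p of 0.603 with an estimated correlation. AP37 fell by 8.01 ± 1.43 and EAT1 (Os04g0599300), a tapetum transcription factor, fell by 2.27 ± 0.29.

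The photosynthesis list went up in WA at UN (21 of 82 higher, 5 lower; median 0.40, adjusted p = 0.0425, and 0.84 with an estimated correlation). Histones (5 of 47 lower, 0 higher, and 2 lower adjusted over the list alone; median −0.39, adjusted p = 0.0234) and cell division genes (34 of 435 lower, 22 higher; median −0.29, adjusted p = 0.00243) went down, with an adjusted p of 0.804 and 0.607 with an estimated correlation. Quantile normalization ended the call of the histones. The alternative oxidases AOX1b (Os04g0600300) and AOX1d (Os02g0318100), which pass electrons in mitochondria around the cytochrome path, rose by 4.89 ± 0.69 and 4.49 ± 0.71 (the array describes the latter as alternative oxidase 1a), although the list of 4 was not called by camera (adjusted p = 0.114, and 0.000282 by fry). AOX1d was above background on 2 of 3 T65 arrays. A phenylalanine ammonia-lyase (Os02g0627100) rose by 7.26 ± 0.86 and the wound-induced protease inhibitor WIP1 (Os01g0132000) by 7.20 ± 0.45.

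The number of called genes at UN was lowest in W11 and highest in WA. It was 3391 in BT (1826 higher, 1565 lower), 1990 in CW (1074 and 916), 3875 in LD (2310 and 1565), 825 in W11 (559 and 266) and 4618 in WA (2987 and 1631). With the slide as a block the counts were 3379, 1794, 4203, 890 and 4676, of which 2905, 1537, 3524, 777 and 4073 were among the genes called without it. Where a slide held an array of the line and an array of T65, the genes were also called without that pair. Of these genes, 97.3% went the same way between the 2 arrays left out in BT, 96.5% in CW, 99.1% in LD and in WA, and 93.7%, 97.9% and 92.2% on the 3 slides of W11. Without the 4 arrays chosen by eye the counts were 3974, 2316, 4030, 887 and 4728. Without CW UN replicate 2, CW had 1324 called genes. Normexp called 1481 higher and 638 lower in BT, 1294 and 360 in CW, 1294 and 910 in LD, 278 and 80 in W11 and 1895 and 1010 in WA.

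**Figure D3:**
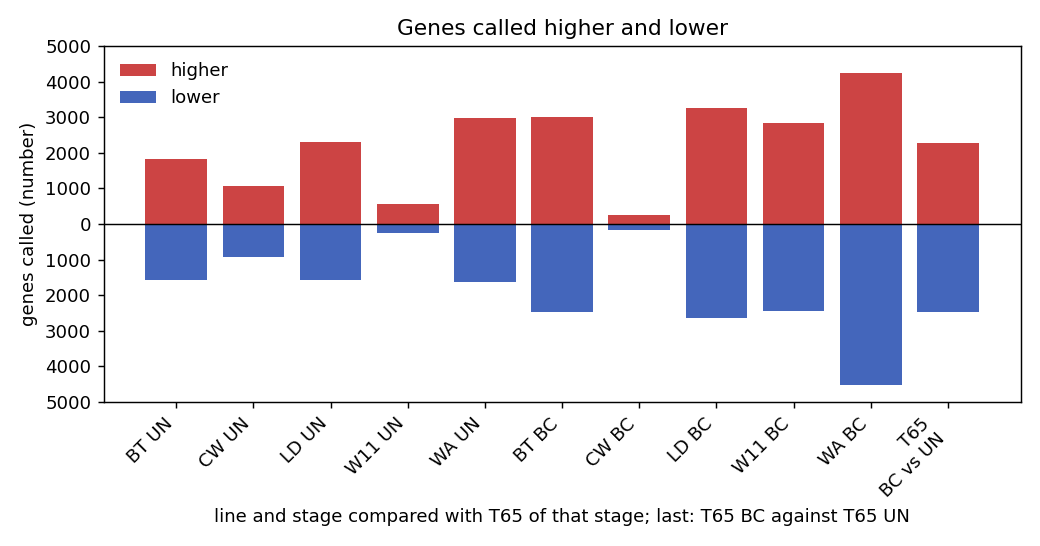
Bars give the number of genes called higher and lower in each comparison (adjusted p under 0.05 and at least 2-fold; n = 3 arrays per group). The counts run from 429 genes in CW at BC to 8753 in WA at BC, and under normexp the direction with more genes turns from higher to lower in BT, CW, LD and W11 at BC, and from lower to higher for the T65 stage change.

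At UN, 65 genes were called the same way in all 5 lines, 38 higher and 27 lower. A sulfate transporter (Os01g0719300) was higher by a mean of 4.75 over the lines, from 1.92 ± 0.48 in W11 to 6.53 ± 0.48 in LD. WRKY24 (Os01g0826400), a transcription factor, was higher by a mean of 4.19, from 2.19 ± 0.84 in LD to 8.11 ± 0.84 in WA, and was above background on 2 of 3 BT arrays. EFA27 (Os04g0511200), described as an EF-hand protein of abscisic acid response, was higher by a mean of 3.36. An EF-hand calcium-binding gene (Os01g0765600) was lower by a mean of −3.35 (largest adjusted p = 0.0051), and an Ole e 1 family gene (Os09g0508200), of the pollen allergens, by −3.18. A glycoside hydrolase of family 20 (Os05g0415700) followed at −2.53. The sulfate transporter and the EF-hand gene Os01g0765600 moved the same way between the stages of T65. In log2 signal minus the 75th percentile, the transporter lay from −5.13 to −3.61 on the T65 UN arrays and from 1.59 to 2.77 at BC. The EF-hand gene lay from −2.12 to −1.86 at UN and from −6.02 to −4.71 at BC. Their changes at UN thus cannot be told apart from the stage change. Farther down were 2 sucrose synthase genes, Os04g0309600 at −1.88 and Os04g0249500 at −1.53; with normexp they were at 0.27 and 0.08 in BT and at 0.58 and 0.19 in CW.

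Independent calls would give 0.015 genes higher and 0.00193 lower in all 5 lines. In 5 simulations of each kind without any change the highest count was 6 with shared T65 arrays and 4 with shared slides or scan days as well. Part of the excess may come from the shared arrays and slides. Neither figure allows for changes that some of the lines share, and 244 genes were called higher and 374 lower in at least 4 lines. They therefore cannot tell how many of the 65 genes changed in every line. Without T65 UN replicate 3, 37 genes were called in all 5 lines, and without the 4 arrays chosen by eye 81. Normexp called 12 higher and 11 lower, and the filter on all 36 arrays 30 and 9. The F test among the 5 CMS lines called 10115 genes (38% of those tested), and 625 genes were called higher in 1 line and lower in another. WA had 2504 genes called in no other line, LD 800, BT 416, W11 188 and CW 139; these counts are not tests of a difference between lines.

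At BC, pectin enzyme, allergen and expansin genes rose in BT, LD and W11, and starch and respiration genes rose with them. These comparisons ask how each CMS line differs from T65 once pollen is bicellular. A gene described as Szp (Os05g0226000) rose by 12.09 ± 1.62 in BT, 13.22 in LD and 13.96 in W11 (adjusted p = 1.9e-06, 4.61e-07 and 2.61e-07), and a disease resistance response protein (Os03g0809000) by 11.50 ± 1.69, 12.81 and 13.12. A pectin methylesterase (Os04g0458900), an enzyme of cell wall pectin, rose by 11.99 ± 1.26 in W11. A gene described as ZmGR1a (Os02g0662100) fell, with −9.11 ± 1.05 in BT, −7.86 in LD and −7.46 in W11, as did a Bet v I family gene (Os04g0465600), with −7.99 ± 0.90 in BT, −7.42 in LD and −6.67 in W11. An AWPM-19-like family gene (Os07g0422100) was the most lowered gene of LD named by the rule, at −8.28. The Szp gene and Os03g0809000 were above background on 1 of 3 T65 arrays, and the ZmGR1a gene on 1 of 3 BT arrays.

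Of 81 pectin enzymes, 31 were higher and 8 lower in BT (33 and 8 adjusted over the list alone; median 0.27, adjusted p = 0.0171), 39 and 11 in LD (median 1.13, 0.00012) and 37 and 9 in W11 (median 0.72, 4.4e-06), with an adjusted p of 0.67, 0.607 and 0.603 with an estimated correlation; under normexp the medians were −0.35, −0.16 and −0.16, and the call in BT was lost there and with the slide as a block. Of 74 pollen allergens and expansins, 32 were higher and 9 lower in BT (median 1.12, adjusted p = 0.00693), 34 and 11 in LD (median 1.41, 0.00243) and 31 and 9 in W11 (median 0.73, 0.000564), with an adjusted p of 0.749, 0.675 and 0.67 with an estimated correlation and medians of −0.05 in LD and −0.25 in W11 under normexp. The beta-expansin Os03g0106900 rose by 10.84 ± 1.5, 11.62 and 11.96, and was above background on 1 of 3 T65 arrays. A pectate lyase (Os06g0584000) rose by 8.97 ± 1.23, 9.71 and 10.45. Actin cytoskeleton genes were not called as a list by camera (adjusted p by fry = 0.0119, 0.000753 and 0.000116 in BT, LD and W11), with 17 of 90 higher and 7 lower in BT, 22 and 10 in LD and 23 and 10 in W11, and the pollen actin-depolymerizing factor Os07g0484200 rose by 6.92 ± 1.15 in BT and 8.37 in LD.

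Of 24 starch synthesis genes, 10 were higher and 1 lower in BT (median 0.94, adjusted p = 0.00152), 12 and 2 in LD (median 1.03, 0.011) and 10 and 1 in W11 (median 0.83, 0.00287), with an adjusted p of 0.607, 0.608 and 0.607 with an estimated correlation. AGPL4 (Os07g0243200), a subunit of the ADP-glucose enzyme of starch synthesis, rose by 3.48 ± 0.47 in BT, 4.14 in LD and 4.70 in W11, and GBSSI by 3.51 ± 0.89, 3.21 and 3.25, whereas SSIIa (Os06g0229800), a starch synthase, fell, with −1.62 ± 0.34, −2.00 and −1.62. Of 46 respiratory complex genes, 18, 20 and 12 were higher in BT, LD and W11 and 0 lower (median 0.86, 0.96 and 0.80; adjusted p = 5.23e-09, 1.34e-09 and 5.36e-10, and 0.607 in each with an estimated correlation). A cytochrome oxidase copper chaperone (Os02g0794600) rose by 2.97 ± 0.22, 3.03 and 2.45. Mitochondrial carriers and import genes went up in BT and LD (9 of 65 higher and 3 lower in each; median 0.42 and 0.36, adjusted p = 0.00217 and 0.00659, and 0.607 in both with an estimated correlation).

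The list heat shock and chaperones went up in BT (35 of 164 higher, 9 lower; median 0.13, adjusted p = 0.0165) and LD (37 and 5; median 0.19, 0.00837), with an adjusted p of 0.603 in both with an estimated correlation and medians of −0.05 and −0.04 under normexp. A small heat shock protein (Os11g0244200) rose by 7.69 ± 0.75 in BT and 8.21 in LD. Histones went down in BT (15 of 47 lower, 2 higher; median −0.71, adjusted p = 7.39e-05), LD (16 and 2; median −0.70, 0.00021) and W11 (16 and 2; median −0.85, 0.000117), with an adjusted p of 0.608, 0.635 and 0.61 with an estimated correlation. Cytosolic ribosomal proteins went down in W11 (1 of 240 lower, 1 higher; median −0.40, adjusted p = 2.79e-06, and 0.776 with an estimated correlation).

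Tapetum regulators went down at BC in BT (3 of 12 lower; median −0.64, adjusted p = 0.0453), LD (4; median −0.78, 0.0147) and W11 (3; median −0.71, 0.0428), with 0 higher and an adjusted p of 0.608, 0.607 and 0.608 with an estimated correlation; the calls in BT and W11 were lost with normexp and with the slide as a block. The pollen wall and sporopollenin list went down in BT (4 of 13 lower; median −1.07, adjusted p = 0.0323) and LD (5; median −0.80, 0.0315), with 0.67 in both with an estimated correlation, and both calls were lost with normexp, as was that in LD with the slide as a block. Phenylpropanoid and flavonoid genes went down in LD (16 of 44 lower, 4 higher; median −0.62, adjusted p = 0.0337, and 0.67 with an estimated correlation), a call lost with normexp, with no filter on dim probes and with the slide as a block. The changes of these lines ran alike across genes, with a correlation of 0.92 for BT and LD, 0.92 for LD and W11 and 0.83 for BT and W11, against 0.45, 0.48 and 0.50 simulated. BT and LD shared 2510 genes higher and 1997 lower (366 and 247 expected of independent calls), and part of the excess may come from the shared T65 arrays. Of the 1961 genes that rose in all 3 lines, 76.5% were higher on the array T65 BC 1 than on T65 BC 2 and 3, against 39.1% of all genes.

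In CW at BC, heat shock and photosynthesis genes rose, and fewer genes were called than in any other comparison with T65. An ethylene-responsive transcriptional coactivator (Os06g0592500) rose by 7.27 ± 0.30 (adjusted p = 3.82e-15), a MuDR transposase family gene (Os07g0102900) by 6.80 ± 0.72 and a CONSTANS-like gene described as CO9 (Os03g0139500) by 5.44 ± 0.97, and a DnaJ family gene (Os04g0675400) fell by 5.80 ± 0.23 (adjusted p = 1.86e-15). The MuDR gene and CO9 were above background on 1 of 3 T65 arrays. Of 164 genes of the list heat shock and chaperones, 23 rose and 1 fell (29 and 2 adjusted over the list alone; median 0.05, mean 0.41, adjusted p = 3.19e-09, and 0.0144 with an estimated correlation), with a median of −0.12 under normexp; a small heat shock protein (Os01g0136200) rose by 3.68 ± 0.32. Of the photosynthesis list, 27 of 82 rose and 1 fell (29 and 2 adjusted over the list alone; median 0.39, adjusted p = 3.73e-12, and 0.603 with an estimated correlation), with a median of −0.18 under normexp.

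Other lists in CW at BC went up by small amounts, with limma calling 1 of the pectin enzymes and 0 members of the others, of which 15, 5, 0 and 10 were higher and 4, 0, 2 and 7 lower at an unadjusted p under 0.05. They were pectin enzymes (median 0.22, adjusted p = 4.33e-05), pollen allergens and expansins (0.33, 0.00103), respiratory complexes (0.16, 0.000473), mitochondrial carriers and import (0.10, 0.0254) and cytosolic ribosomal proteins (0.12, 4.01e-05), with an adjusted p of 0.607, 0.67, 0.675, 0.61 and 0.813 with an estimated correlation. Under normexp the pectin enzymes had a median of −0.51 and lost the call, and the allergens had a median of −0.17. Quantile normalization ended the calls of the carriers and the ribosomal proteins, and the slide as a block those of the respiratory complexes and the carriers. Of the 1961 genes that rose at BC in all of BT, LD and W11, 92.8% were higher on the array CW BC 3 than on CW BC 1 and 2, against 58.8% of all genes.

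In WA at BC, most cytosolic ribosomal protein genes fell, and more genes were called than in any other comparison with T65. A thaumatin-like protein (Os03g0663400) rose by 10.31 ± 0.69 (adjusted p = 2.67e-12), the GRAB2 gene by 8.97 ± 0.79 and a leucine-rich repeat gene (Os04g0605300) by 8.86 ± 0.98. A gibberellin-regulated protein (Os05g0432200) fell by 11.60 ± 0.72 (adjusted p = 5.66e-13), a gene with a lipid transfer protein domain (Os04g0415900) fell by 10.86 ± 0.59 and a caleosin (Os06g0254600), an oil body protein, fell by 10.70. The thaumatin-like protein was above background on 2 of 3 T65 arrays, Os04g0605300 on 1 of 3, Os05g0432200 on 2 of 3 WA arrays and the caleosin on 1 of 3.

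Of 240 cytosolic ribosomal protein genes, 179 fell in WA at BC and 0 rose (median −1.26, adjusted p = 1.98e-31, and 0.603 with an estimated correlation). Ribosomal protein S10-1 (Os01g0962600) fell by 3.08 ± 0.15 and L30 (Os01g0812800) fell by 2.98 ± 0.27. Of 47 histones, 20 fell and 0 rose (median −0.85, adjusted p = 0.00194, and 0.67 with an estimated correlation), and cell division genes went down (137 of 435 lower, 30 higher; median −0.31, adjusted p = 0.00116, and 0.607 with an estimated correlation), with the F-box gene Os08g0195800 at −6.77 ± 0.32. Tapetum regulators (5 of 12 lower, 0 higher; median −1.14, adjusted p = 0.0157) and pollen wall genes (7 of 13 lower, 1 higher; median −1.90, adjusted p = 0.0203) went down, with an adjusted p of 0.607 and 0.61 with an estimated correlation, and EAT1 fell by 5.89 ± 0.29. Mitochondrial carriers and import genes went down (22 of 65 lower, 4 higher; median −0.23, adjusted p = 0.0223, and 0.61 with an estimated correlation), a call lost with normexp.

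Single members of lists that camera did not call also changed in WA at BC. Markers of perianth and carpel, organs outside the anther, were higher, with 4 of 8 called and 0 lower (median 1.83, adjusted p = 0.0656, and 0.000116 by fry), among them MADS1 (Os03g0215400) at 4.58 ± 0.66 and MADS6 (Os02g0682200) at 3.24 ± 0.42. Of starch genes 10 of 24 fell and 2 rose (adjusted p = 0.0614), with SSIIa at −6.93 ± 0.34, AGPL4 at −3.91 ± 0.47 and GBSSI (Os06g0133000) at −3.69 ± 0.89. Among 17 sugar transport and invertase genes 8 rose and 3 fell (adjusted p = 0.312), with the monosaccharide transporter listed here as MST8 (Os01g0567500) at −9.71 ± 0.49, the cell wall invertase listed here as CIN3 (Os04g0413200) at −7.98 ± 0.97 and MST3 (Os07g0106200) at 7.29 ± 0.73. The 2 pollen MADS genes of the MIKC* type both fell, and MADS63 (Os06g0223300) fell by 7.36 ± 1.06, whereas both were higher in LD and in W11 at BC and in BT and LD at UN. Allergens and expansins had 13 of 74 higher and 20 lower (adjusted p = 0.488), heat shock genes 16 of 164 and 44 (0.0758), and respiratory complexes 3 of 46 and 5 (0.1).

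At BC the called genes numbered 5475 in BT (2990 higher, 2485 lower), 429 in CW (246 and 183), 5915 in LD (3264 and 2651), 5297 in W11 (2841 and 2456) and 8753 in WA (4226 and 4527). With the slide as a block the counts were 4748, 253, 5140, 5595 and 8761, of which 4371, 222, 4869, 5257 and 8112 were among the genes called without it. Of the genes called without the line array and the T65 array of a slide they share, 96% went the same way between these 2 arrays in BT, 77.7% in CW, 98% in LD, 99.1% in WA, and 94.7%, 99.5% and 98.4% on the 3 slides of W11. Without the 4 arrays chosen by eye the counts were 6294, 520, 6573, 6035 and 7998. CW had 773 called genes without T65 BC replicate 1 and 281 without T65 BC replicate 3, and 200 with only the groups compared. In simulations without any change, 1 comparison at BC gave up to 191 called genes with shared T65 arrays. With shared slides as well it gave up to 201, and with shared scan days 214. The 429 genes of CW may therefore hold many false calls. Normexp called 1484 higher and 2308 lower in BT, 124 and 132 in CW, 1612 and 2436 in LD, 1522 and 1856 in W11 and 1827 and 4545 in WA.

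**Figure D4:**
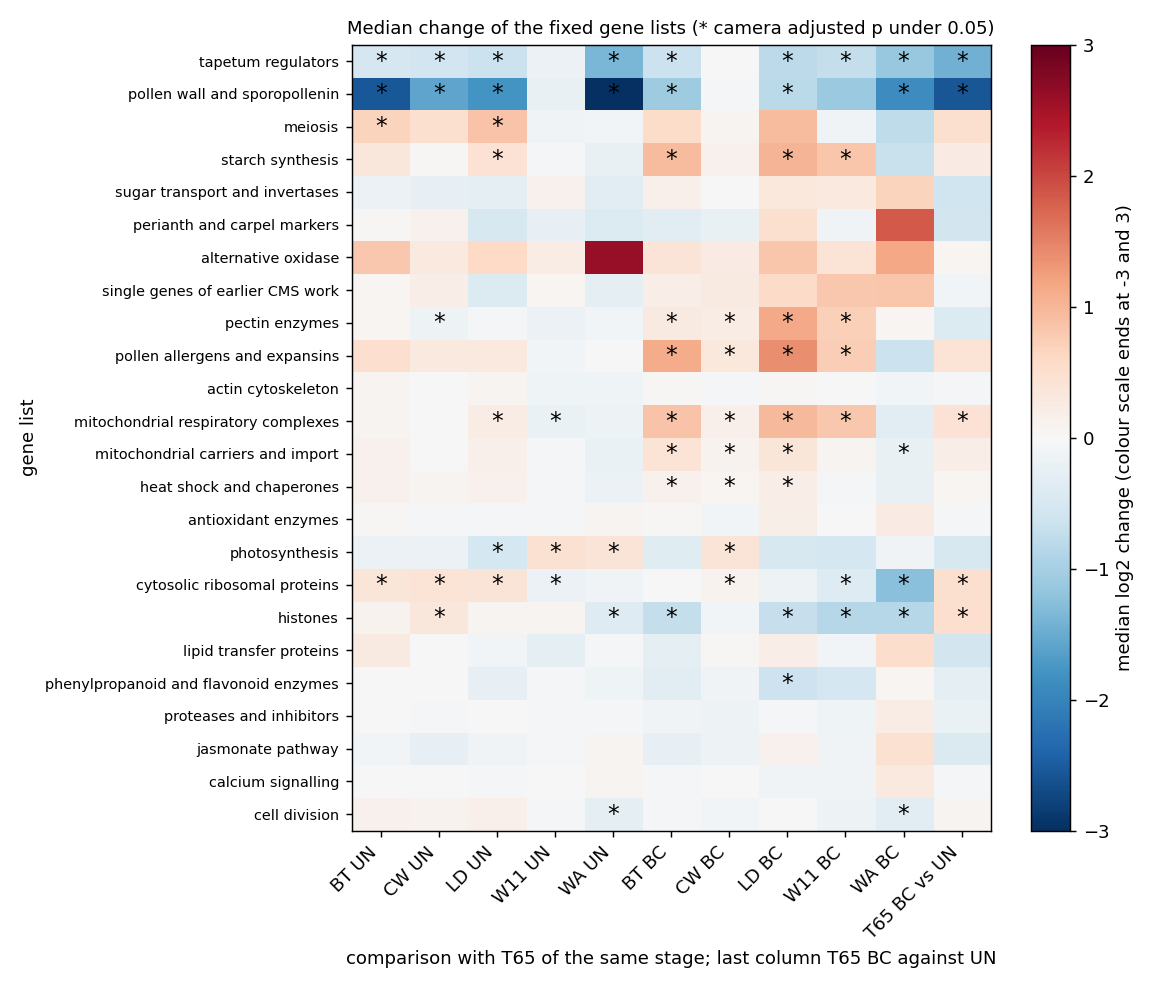
Colour gives the median log2 change of each list of at least 3 genes (rows) in the 10 comparisons with T65 and in the T65 stage change (columns), and a star marks camera's adjusted p under 0.05 with the preset correlation. The cytosolic ribosomal proteins reach −1.26 in WA at BC. With normexp, 48 of the 264 medians change sign from 0.1 or more in size, among them those of pectin enzymes in CW at UN and of pectin enzymes, allergens, heat shock genes and, in CW, photosynthesis genes at BC. Normexp also moved the median of all genes in most comparisons, and 0 of camera's list calls turned direction with it.

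At BC, 63 genes were called the same way in all 5 lines, 28 higher and 35 lower. A calmodulin-like gene (Os01g0810300) was higher by a mean of 4.66, from 2.75 ± 0.52 in CW to 5.64 ± 0.52 in W11. A sodium and sulphate symporter family gene (Os08g0503700) was higher by a mean of 4.23, with 1 of 3 T65 arrays above background and with normexp values of −0.33 in BT and −0.82 in CW. A small heat shock protein, hsp17.3 (Os03g0266900), was higher by a mean of 3.72, from 1.39 ± 0.38 in W11 to 5.87 ± 0.38 in LD, and pyruvate decarboxylase (Os01g0160100), an enzyme of ethanol fermentation, by 3.71, with normexp values of −0.46 in CW and −0.26 in WA. An esterase (Os11g0239500) was lower by a mean of −3.15, and 2 genes described as ThiC, an enzyme of thiamine synthesis, by −2.85 (Os03g0679700) and −2.42 (Os12g0270200).

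Independent calls would give 0.0572 genes higher and 0.0266 lower in all 5 lines at BC. In 5 simulations of each kind without any change the highest count was 10 with shared T65 arrays, 11 with shared slides as well and 9 with shared scan days. Part of the excess may come from the shared arrays and slides. As at UN, neither figure allows for changes that some of the lines share, and 486 genes were called higher and 807 lower in at least 4 lines. How many of the 63 genes changed in every line cannot be told from them. The count of 63 fell to 33 without CW BC replicate 3, 31 without T65 BC replicate 2, 29 without T65 BC replicate 3 and 27 with the slide as a block, and was 129 without T65 BC replicate 1 and 74 without the 4 arrays chosen by eye. Normexp called 8 higher and 43 lower, and a fit of only the groups compared called 29. The F test among the CMS lines called 14969 genes (56.2%), and 1496 genes were called higher in 1 line and lower in another. WA had 4915 genes called in no other line, W11 444, BT 434, LD 354 and CW 76. BT and WA shared 643 genes higher and 967 lower (474 and 422 expected) and had 1168 genes called in opposite directions.

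Whether a line's change from T65 differed between the stages was tested by the interaction. The alternative oxidase listed here as AOX1a (Os04g0600200), which the array describes as alternative oxidase 1c, was called there in 4 lines. At BC it was higher in BT by 5.08 ± 0.42 (adjusted p = 1.44e-09), in LD by 5.01 and in W11 by 4.55, and it fell by 2.13 in WA, while in CW it was at 1.38 (adjusted p = 0.0673). At UN it was called in BT alone, at 1.19 ± 0.42 (adjusted p = 0.0352). There the array BT UN 1 was at 0.37 (log2 signal minus the 75th percentile), within the T65 range of 0.19 to 0.38. The UN arrays of LD (0.81 to 1.62) and WA (0.9 to 1.33) all lay above that range without a call, and those of CW and W11 did not. The interaction was 3.89 ± 0.59 in BT, 4.06 in LD, 4.79 in W11 and −2.86 in WA (largest adjusted p = 0.000495), and 1.38 in CW (adjusted p = 0.15). In T65, AOX1a fell by 1.14 from UN to BC. The interaction was called for 5305 genes in BT (2654 higher, 2651 lower), 1692 in CW (683 and 1009), 5897 in LD (2756 and 3141), 4804 in W11 (2741 and 2063) and 5454 in WA (1863 and 3591). Normexp called 1074 higher and 3565 lower in BT, 377 and 8365 in CW, 1274 and 2427 in LD, 1333 and 1444 in W11 and 809 and 2997 in WA. With the slide as a block CW had 1021, and without the 4 arrays chosen by eye the counts were 5505, 1677, 6182, 5679 and 4943.

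The single genes of earlier CMS work were called in no line. DCW11 (Os02g0149800), a mitochondrial protein phosphatase tied to sterility of the CW type, was called in no comparison and was at 0.96 ± 0.13 in W11 and 0.80 in WA at UN (adjusted p = 3.61e-05 and 3.17e-05), under 2-fold. The locus listed here as RF2 (Os02g0274000), the restorer gene of the LD type, was at −0.42 ± 0.14 in LD at UN and 0.57 at BC (adjusted p = 0.0275 and 0.00197), with an interaction of 0.99 ± 0.20 (adjusted p = 0.000468), and at BC it was at 0.86 in W11 (adjusted p = 3.34e-05) and −0.57 in WA, all under 2-fold. The array describes no product for it or for the locus listed here as RMS (Os04g0475900), the restorer gene of the CW type. In T65, RMS was above background on 3 of 3 arrays at UN and 0 of 3 at BC, and its change from UN to BC was −2.39 ± 0.68 and turned to 1.30 with normexp. As a list, these genes were not called in any comparison by camera, and fry called them in LD and W11 at UN and in CW, LD and W11 at BC. Pentatricopeptide repeat genes, a family that holds many restorers, were found only by words in the array's descriptions, which matched 2 loci. Members described otherwise were not examined. The 2 loci were too few to test, and 1 of them (Os04g0463300) was at 2.51 ± 0.42 in LD at UN, 2.07 in W11 at BC and −1.59 in WA at BC.

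Several lists were called in no comparison by camera with the preset correlation. These were sugar transport and invertases, perianth and carpel markers, alternative oxidase, the single genes of earlier CMS work, actin cytoskeleton, antioxidant enzymes, lipid transfer proteins, proteases and inhibitors, jasmonate pathway and calcium signalling. Fry called each of them in at least 1 comparison with T65, such as sugar transport in BT at UN (adjusted p = 0.0027), where camera with the slide as a block called it too (0.0317). Within them single members changed strongly. A peroxidase (Os02g0741200) rose by 11.75 ± 1.35 in W11 at BC, a calmodulin-like gene (Os12g0228800) by 9.49 ± 0.83 there, and a subtilisin-like protease (Os08g0326700) fell by 7.91 in WA at BC.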

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

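The tests of slides, the splits of the interaction with the common change taken off, and the test of whether BT, CW and LD at UN follow the stage change of W11 were chosen after the result was seen.

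The difference between a line's change at BC and its change at UN, tested as an interaction, was called for 5305 genes in BT, 1692 in CW, 5897 in LD, 4804 in W11 and 5454 in WA. Of 100 splits of each line's 12 arrays between line and T65, the real one included, 2 gave as many genes in BT (highest other 5483), 2 in CW (1765), 1 in LD (highest other 5771) and 3 in W11 (5636). In WA, 12 of 100 splits did, with a highest other of 11827 when all 3 arrays were exchanged at BC. Exchanging arrays at 1 stage brings in the sum of the changes at both stages, which is a structure of the samples. These splits ask whether line and T65 arrays are alike at all, so they leave the interaction undecided in each line. Once the line's mean change over both stages was taken off its arrays, 1 of 100 of the same splits, the real one, gave as many genes in each line, with a highest other of 3408 in BT, 1054 in CW, 3380 in LD, 2494 in W11 and 3047 in WA. The real grouping thus gave more genes than every other split drawn. Exchanging all 3 arrays at 1 stage then gives no interaction by construction, so that split is no test here. The splits did not keep the slides together, and with the slide as a block CW had 1021 genes.

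For AOX1a (Os04g0600200) the interaction was 3.89 in BT, 4.06 in LD, 4.79 in W11 and −2.86 in WA. Among the 5 CMS lines, the F test found 10115 genes that differ at UN and 14969 at BC. The highest of the other 99 regroupings of the 15 arrays called 3318 and 12621 (1 of 100 as large in each, the real one). This goes against the 5 groups being alike. It does not show how many of the counted genes are false calls. Of 100 regroupings of the 18 arrays of a stage into 6 groups, 2 gave as many genes called in all 5 lines at UN (65, highest other 102) and 2 at BC (63, highest other 611). They ask whether all 6 groups are alike, which the F test already goes against. They therefore cannot tell whether genes came to be called in all 5 lines by chance. A regrouping with 611 points to a structure of the samples. The regroupings did not keep the slides together, and with the slide as a block 27 genes were called in all 5 lines at BC. The comparisons of 3 arrays with 3 have 10 splits each, too few for a share under 0.05, and in each 1 split, the real one, gave as many genes. The real count and the highest other were 3391 and 21 in BT, 1990 and 144 in CW, 3875 and 0 in LD, 825 and 43 in W11 and 4618 and 3 in WA at UN, 5475 and 323 in BT, 429 and 375 in CW, 5915 and 78 in LD, 5297 and 6 in W11 and 8753 and 320 in WA at BC, and 4769 and 1 for the T65 stage change. The array also carries probes for microRNA genes, which no comparison above uses, and 33 of the 297 that passed the filter were called in at least 1 of the 10 comparisons with T65, 5 of them for a mature sequence.

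The changes of BT, CW and LD at UN ran along the change between the stages. The T65 UN arrays that both changes share give at most 8.2% of the observed covariance in simulations, which argues against them as the whole cause, and slides do not account for the whole of it, since at least 96.5% of the genes called without the arrays of a shared slide went the same way on that slide. In W11, which shares no array with these comparisons, the stage change went the same way for 85.2% of the called genes of BT, 78.9% of CW and 89.4% of LD. The share was 62.4% in WA at UN, and 45.2% of all genes were higher at BC in W11. Across genes the correlation with the W11 stage change was 0.55 in BT, 0.40 in CW, 0.63 in LD and 0.22 in WA. These are lower than those with the T65 stage change, which shares arrays. The W11 UN arrays lay on the same slides as the T65 UN arrays. A slide effect could therefore enter both changes, and the W11 values are not free of it. A candidate explanation is that anthers of these lines were further along in development than those of T65 when they were taken. A difference in the lines' own course of development stays open as well and was not tested.

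At BC, 1961 genes were raised in BT, LD and W11 together. The T65 arrays do not account for the whole of it, since 79.1% of these genes were also at least 2-fold higher in each of the 3 lines than in CW at BC, and slides do not either, since at least 94.5% of the genes raised in all 3 lines without the arrays of a shared slide were higher on that slide. Whether these anthers may have been further along than those of T65 cannot be told apart from an effect of the lines, since 72.2% of the genes were higher at BC than at UN in each of the 3 lines and in CW, which lies between the bounds set for and against it. These genes varied among replicates of the other groups too, with 76.5% of them highest among the T65 arrays on T65 BC 1, against 39.1% of all genes, and 92.8% highest among the CW arrays on CW BC 3, against 58.8%.

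In CW at BC, 429 genes were called, and clock genes were among them. Simulations without any change gave up to 214 called genes in 1 comparison at BC, so many of the 429 may be false calls. Slides could have part in it, since 77.7% of the genes called without the arrays of the 1 shared slide (CW BC 2 and T65 BC 1) went the same way there, and with the slide as a block 253 genes were called, 222 of them among the 429. Another time of day of collection could have part in it, as 3 of 10 clock genes were called, the morning gene LHY (Os08g0157600) at 3.63 and the evening genes PRR1 (Os02g0618200) at −1.07 and GI (Os01g0182600) at −1.21; this lies between the bounds set for and against it and cannot be told apart from an effect of the line. LHY was also called higher in 6 other comparisons, at 1.06 to 2.54, so a higher LHY is not particular to CW at BC. In W11 at UN, 1 of 10 clock genes was called higher (LHY, 2.34) and 1 lower, the evening gene FKF1 (Os11g0547000; −1.27). Whether the time of day had part there was not tested. In W11 at BC GI (−0.63) and FKF1 (−0.86) were lower too, under 2-fold. Without the array CW BC 3, 68.5% of the genes were called in the same direction, which leaves open how far that array carries the result.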

How the results depend on the processing

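The fit without 4 arrays and the comparison of calls lost with normexp by level were chosen after the results were seen; the other alternatives were planned. The counts not named here stayed within 1.5 times the reported ones under all of them. Of 7690 alternative values of the 415 named changes, 7376 kept their direction and side of the threshold, 286 were no longer called, 8 were newly called and 20 reversed, all 20 with normexp. Of the 415, 61 were no longer called with normexp, 33 with only the groups compared, 20 with the slide as a block and 9 with the scan day. Without CW BC 3, 12 of 32 were no longer called. Not each of these genes is marked where it is named. Signal over local background had medians of 3.2 to 8.62. Of the calls in all 11 comparisons, ranked by the mean level of the gene, normexp lost 68.9% among the lowest 8882 genes, 26.9% among the next 8881 and 9.8% among the highest 8882, and the change turned sign for 23.1%, 0.5% and 0%.

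With normexp the counts were 2119 in BT, 2204 in LD, 358 in W11 and 2905 in WA at UN, 256 in CW and 3378 in W11 at BC, 2955 for the T65 stage change, 8742 for the interaction in CW, 3701 in LD and 2777 in W11, 23 for all 5 lines at UN and 6690 for the F test at UN. The interaction in CW rose, from 1692, and 8365 of its genes were lower. There normexp moved the median of all genes to 0.48 at UN and −0.37 at BC, a shift of all genes in that direction. The other counts fell. Calls of dim genes were lost most in the 11 comparisons, as above, and the cause was not tested further. With the filter on all 36 arrays, which tests fewer genes, they were 2125 in BT, 1288 in CW, 2439 in LD and 2932 in WA at UN, 3594 in BT, 3859 in LD and 3382 in W11 at BC, 2915 for the T65 stage change and 39 for all 5 lines at UN. With the slide as a block they were 253 in CW at BC, 1021 for the interaction in CW and 27 for all 5 lines at BC, and with only the groups compared, which leaves fewer samples, 200 in CW at BC and 29 for all 5 lines at BC. For the slide block the cause was not tested. With normexp camera called 73 list tests, lost 12 of its calls and turned the direction of 0. Camera called 1 list test with an estimated correlation in place of 68, and without the filter on dim probes it no longer called phenylpropanoid and flavonoid enzymes in LD at BC (adjusted p = 0.0749 in place of 0.0337). The cause was not tested.

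Named values that reversed with normexp were, at UN, Os04g0309600 at 0.27 in BT and 0.58 in CW and Os04g0249500 at 0.08 and 0.19. At BC they were Os08g0503700 at −0.33 in BT and −0.82 in CW, Os11g0438700 at −0.70 in BT, −0.92 in CW and −0.61 in LD, Os06g0187500 at −0.02, −0.72 and −0.11 in these lines, Os11g0127800 at −0.22 in BT, −0.54 in LD and −0.38 in WA, Os01g0160100 at −0.46 in CW and −0.26 in WA, Os07g0486000 at −0.09 in W11 and Os04g0600300 at −0.63 in WA. Os04g0475900 was at 1.30 for the T65 stage change. For these single genes the cause was not tested.

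Leaving out each array in turn, which leaves fewer samples, gave 2675 to 3849 genes in BT, 1324 to 2325 in CW, 3167 to 4180 in LD, 582 to 822 in W11 and 4171 to 4504 in WA at UN. At BC it gave 4435 to 6219 in BT, 281 to 773 in CW, 4948 to 6499 in LD, 4426 to 5988 in W11 and 7891 to 8973 in WA, and for the T65 stage change 3552 to 5243. The interactions ran from 4746 to 5643 in BT, 1161 to 2000 in CW, 5258 to 6527 in LD, 3905 to 5563 in W11 and 4797 to 5808 in WA. Genes called in all 5 lines ran from 37 to 84 at UN and 29 to 129 at BC, and the F test from 9623 to 10294 and 14541 to 15459. The counts moved by over 1.5 times without CW UN 2 (CW 1324), T65 UN 3 (all 5 lines 37), T65 BC 1 (CW 773, all 5 lines 129), T65 BC 3 (CW 281, all 5 lines 29), T65 BC 2 (all 5 lines 31) and CW BC 3 (all 5 lines 33). With the replicate number as a block the counts were 3466, 2025, 3949, 843 and 4692 at UN and 5530, 454, 5979, 5367 and 8847 at BC for BT, CW, LD, W11 and WA, and of camera's list calls that of tapetum regulators in BT at BC was lost (adjusted p = 0.0514 in place of 0.0453). Arrays of different groups that share a number had residuals with a mean correlation of 0.07 at UN (from −0.29 to 0.44, and a mean of −0.03 for other numbers) and 0.12 at BC (from −0.46 to 0.66, and −0.06), and 10 of 18 arrays at UN and 8 of 18 at BC correlated best with an array of their own number. As not every pair was above 0, the numbers were not taken as pairs. Pairs of different groups on 1 slide were all above 0, from 0.01 to 0.44 at UN and from 0.08 to 0.66 at BC. The main fit leaves the slide out, and the counts with the slide as a block are given beside it.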

Other observations

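The observations on clock genes and microRNA probes were chosen after the results were seen.

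Clock genes were higher in WA at BC than in T65, with 8 of 10 called higher and 0 lower. FKF1 (Os11g0547000), an evening gene of the day-length response, was at 2.23 (adjusted p = 1.01e-09, n = 3 per group), PRR95 (Os09g0532400) at 1.76 and PRR73 (Os03g0284100) at 1.59. The genes listed as YABBY1 (Os07g0160100) and DL (Os03g0215200), of the perianth and carpel list, were at 4.53 ± 1.25 (SE) and 1.06 there, and DL was at 1.62 ± 0.21 in WA at UN. The jasmonate pathway had 10 of 33 members higher and 4 lower in WA at BC (adjusted p = 0.225), calcium signalling 42 of 162 and 32 (0.127), antioxidant enzymes 62 of 264 and 38 (0.206), proteases and inhibitors 40 of 149 and 26 (0.196), and lipid transfer proteins 20 of 65 and 12 (0.252), and none of these lists was called by camera. By fry the adjusted p was 0.00125, 7.88e-05, 0.034, 0.00896 and 0.0692.

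Probes for microRNA genes were called at both stages, and at BC the called ones numbered 11 higher and 0 lower in BT, 12 and 1 in LD, 14 and 1 in W11 and 15 and 3 in WA. In W11 at UN and in CW at BC limma called 0, with 2 and 5 at an unadjusted p under 0.05. The 5′ probe of miR160f was at 3.21 in BT, 3.78 in LD and 4.09 in W11, and at −1.05 in WA. The 3′ probe of miR172b was at 3.66 in BT, 2.83 in LD, 3.68 in W11 and 4.39 in WA at BC. At UN it was at −1.69 in BT, −2.77 in CW, −2.31 in LD, −0.65 in W11 and 1.70 in WA. Its T65 stage change was −2.86. The 5′ probe of miR393b was at 3.75 in BT at UN and −5.62 in WA at BC, where the 3′ probe of miR393b was at 0.59 and −5.34. The 3′ probe of miR169c was at 4.38 in WA at BC.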
